A study of Homo sapiens with 6 samples.

How the data were processed

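Gene expression was measured in 293T cells, a human kidney-derived epithelial line, on 6 Agilent microarrays with 2 colour channels. The cells had been infected with a retrovirus made from the pBabe-puro plasmid. The plasmid carried wild-type GATA3 cDNA, GATA3 with arginine 367 changed to leucine (R367L), or GATA3 with a stop codon at that residue (R367-STOP). Every array also held RNA pooled from 3 independent infections with the empty plasmid, which served as the control. Each construct was hybridised on 2 arrays with the channels exchanged. No label says that the arrays of a pair came from separate infections, so each pair was taken as 1 sample and each construct has n = 1. Wild-type GATA3 and R367L carry the same day tag in the labels and R367-STOP carries another, so day and construct cannot be told apart for R367-STOP.

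The deposited values are log ratios of the channels of each array and were read as log2 ratios. The log base is an assumption: the range of the values is too wide for log10, and a natural log could not be excluded. If it were a natural log, every log2 value given here would be too small by the same factor, the folds would be larger, and more genes would pass each limit. With wild type, for instance, the count would lie between the 59 genes reported and the 199 at 1.5-fold. The scanner, background correction, normalization and filters are not given in the sources used here. The array medians lay between -0.018 and 0.008, so the values had already been centred. Between 53 and 581 of the 22575 probes had no value on an array (0.235% to 2.57%). Spot intensities were not used here, so there was no measure of signal over background, no matching on mean expression and no trend in the variance prior.

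The labels name no dyes. Channel 2 over channel 1 is the likely direction of the ratio. Its basis is that both GATA3 transcript probes changed sign with the channel that held the construct, and came out higher with the construct on all 6 arrays once turned. Every array was turned to construct over control. The design required both arrays of a construct to correlate above 0 after turning, and they did not: across genes r was -0.46 for wild type, -0.13 for R367L and -0.13 for R367-STOP. As deposited, the same pairs correlated at 0.46, 0.13 and 0.13, because genes carried a dye effect that was alike on all arrays. The dye effects of different constructs correlated at 0.868 to 0.874. After the dye effect of the other constructs was removed, the turned pairs correlated at 0.34, 0.60 and 0.56. The turning was kept, and the dye effect cancels in the mean of a pair.

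Probes were named from the platform annotation: 17828 had 1 gene symbol, 49 had several and were not used under a name, and 4698 were not listed with a gene here. The gene identifiers of 17797 probes were found in a RefSeq gene table of assembly GRCh38.p14, and the annotation's symbol was kept for the other 31. That table also gave the chromosome and the order of genes. No coordinates are printed, since no genome build is named for the arrays. Probes of a gene were averaged on the log2 scale, giving 13621 genes, of which 13014 had a value on all 6 arrays. Signals of near-identical genes, such as keratins, HSPA1A and HSPA1B, or the MAGEA genes, can be shared between their probes.

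A gene was past the rule when the mean of its pair of arrays was at least 1 in size on the log2 scale (2-fold) and each array alone was at least 1.5-fold in the same direction. Differences between constructs were taken within arrays of the same orientation, with the same limits. With 1 sample per construct these are values with no test and no p-value. Standard errors (SE) are moderated errors from limma 3.58.1 in R 4.3.3, over the 6 arrays with the constructs and a dye term, which left 2 residual degrees of freedom per gene. They cover array-to-array error only, and the number of arrays limits their precision. The median SE was 0.08 for a construct and 0.11 for a difference of constructs. One question had a test: limma, with Benjamini-Hochberg adjustment and a two-sided p, asked which genes differed from 0 in the mean of the 3 constructs. It treats the constructs as separate infected populations and leaves out the spread of the control pool.

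The named genes follow a rule set before the data were examined: GATA3, the 10 largest changes in each direction for each construct, the 5 largest in each direction for each pair of constructs, and up to 4 members of each of 20 gene lists past the rule. Where a list had none, its 2 largest values were given. Genes named outside it are said to have been chosen after their values were seen. List medians were set against 10000 random lists of the same size, as a description of these arrays. These random lists were not matched on expression. The reference genes themselves lay at percentiles 99.98, 97.4 and 99.9 with wild type, R367L and R367-STOP, so a place in the tails is not particular to the theme of a list.

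The scripts were tested on simulated data with 13014 genes. For wild type against empty vector, the rule recovered 97 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 2.5, with 4 false calls. For R367L against wild type it recovered 97 and 100, with 12 false calls. The limma test of the mean of the 3 constructs recovered 72 of 100 genes changed by 1 and 95 of 100 changed by 2, with 2 false calls.

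Alternatives fixed in advance were other fold limits, other demands on array agreement, centring, scaling, separate probes, missing values, noisy genes, robust variance estimates, other choices of genes and leaving out each array or construct. Added after the data had been seen were removal of the dye effect before arrays were compared, leaving out a chromosome 11 segment, leaving out genes with a large dye effect, and scaling before list medians. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.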

Results

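RNA from 293T cells carrying wild-type GATA3, GATA3 R367L or GATA3 R367-STOP was compared with pooled empty-vector RNA on 6 arrays, 2 per construct with the channels exchanged. GATA3 is a zinc finger transcription factor of luminal breast epithelium and T cells. The study concerns GATA3 mutations in breast tumours, and the arrays ask which genes differ when each form of the factor is expressed. Each value is the mean log2 ratio of 1 pair of arrays, and ± gives the array-to-array SE. There is no biological replicate, so no single-construct difference has a replicate check.

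The sign of the GATA3 values is not a finding, since the likely direction of the ratios was chosen from the transcript probes 19284 and 19285; their sizes are. The GATA3 transcript probes 19284 and 19285 gave 1.27 and 1.21 with wild type, 1.71 and 1.72 with R367L, and 1.49 and 1.42 with R367-STOP. Their means correspond to 2.36-fold, 3.28-fold and 2.74-fold. The other GATA3 probe, 14800, gave 0.40, 0.39 and -0.07, and its orientations disagreed, with 1.75 and -0.94 for wild type. Averaged over its probes, GATA3 was 0.96, 1.27 and 0.94 (± 0.09), and only the R367L value was past the rule. The ratios do not tell the vector's transcript from the cell's own, nor give protein levels.

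**Figure D1:**
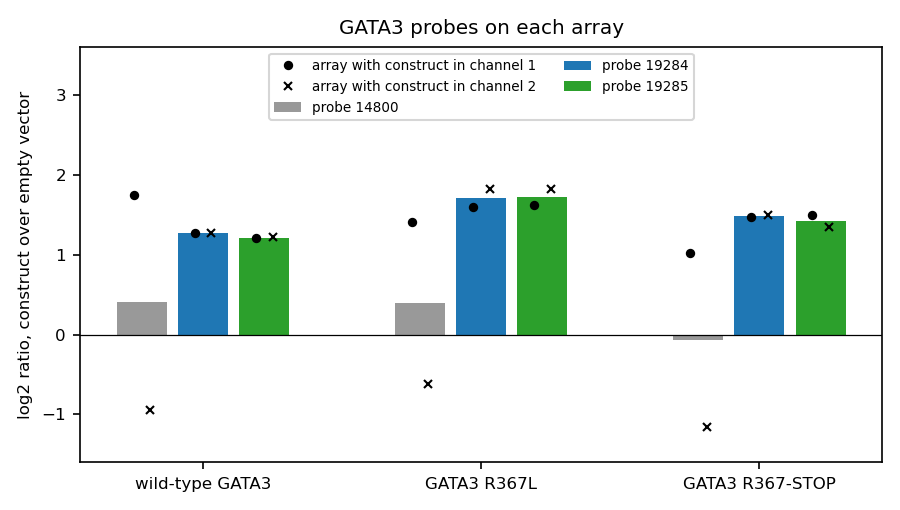
Log2 ratio of construct over empty vector for the 3 GATA3 probes with each construct. Bars are means of 2 arrays and the circle and cross are the arrays with the construct in channel 1 and channel 2; probes 19284 and 19285 lie between 1.21 and 1.72 on average, whereas the arrays of probe 14800 lie on opposite sides of 0.

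With wild-type GATA3, 59 of 13530 genes measured were past the rule, 55 higher and 4 lower, among them members of the keratin, luminal and epithelial junction lists. The largest rises were in DHRS2, a short-chain dehydrogenase/reductase gene, at 4.09 ± 0.09 (17.04-fold), and S100A6, a calcium-binding protein gene, at 3.88 ± 0.09 (14.8-fold). MAL2, which acts in transcytosis in polarised epithelia, rose by 3.81, the simple-epithelium keratin gene KRT19 by 3.78 and the imprinted noncoding RNA H19 by 3.64. LGALS3BP (2.75), S100A16 (2.41), GSDMB (2.20), S100P (2.19) and SERHL2 (2.12) followed. The genes that fell were ASNS, asparagine synthetase, at -1.57 ± 0.07, TIMM17B, a mitochondrial import subunit, at -1.21, CTH, an enzyme of cysteine synthesis, at -1.08, and the lipoxygenase gene ALOX15B at -1.03.

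By the number of members past the rule, keratins, junction genes and luminal genes (with cholesterol genes as many as luminal) came first with wild type; by median, heat shock genes did (0.30). Of 17 keratins measured 4 rose, KRT19, KRT18 (1.97 ± 0.12), KRT8 (1.52 ± 0.11) and KRT4 (1.21), and the list median was 0.11. KRT4, and below ESR1 and CA12, lie outside the naming rule and were chosen after their values were seen. KRT7 averaged 1.26 ± 0.10 without each array passing. Of 26 luminal breast genes 2 rose, the secreted-protein folding gene AGR2 (1.61 ± 0.10) and FOXA1, a transcription factor that opens chromatin (1.39 ± 0.12), and the median was 0.26. XBP1 was at 0.96 and TFF3 at 0.72, and ESR1, the estrogen receptor gene, was at -0.10. Of 22 epithelial junction genes 3 rose, the protease inhibitor genes SPINT1 (1.63) and SPINT2 (1.21) and the adhesion gene EPCAM (1.28), and the median was 0.19. None of that list's cadherin, claudin, occludin or desmosome genes was past the rule with wild type. CDH1, chosen after its value was seen, was at 0.11, and CLDN4 at 0.91. In the region of ERBB2 on chromosome 17, often amplified in breast cancer cells, ERBB2 was at 1.35 with wild type and past the rule, and MIEN1 (0.80), GRB7 (0.75) and MED1 (0.59) were below the limit. With R367L they were 1.81, 1.05, 1.16 and 0.83, and with R367-STOP ERBB2 was -0.17. These 4 genes were chosen after their values were seen. The median of 17 listed genes of the region, ERBB2 among them, was 0.10, 0.23 and 0.02 for the 3 constructs. Their neighbours GSDMB and RPL19 were not among the 17. With wild type and R367L, GSDMB was at 2.20 and 2.71, and RPL19 at 1.16 and 1.43.

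Other lists held few genes past the rule with wild type. Of 20 cholesterol and lipid synthesis genes 2 rose, fatty acid synthase, FASN (1.59 ± 0.10), and its regulator SREBF1 (1.46 ± 0.09), and the median was 0.12. Of 20 heat shock genes 1 rose, HSPA1A (1.74 ± 0.09), with a median of 0.30. WNT5A (1.17) was the 1 of 23 TGF-beta, BMP and WNT genes that rose, and the median was -0.03. RPL19 (1.16) was the 1 of 29 ribosomal protein genes that rose, in a list with a median of -0.07. The transferrin receptor gene TFRC (1.44 ± 0.08) was the 1 of 12 reference genes that rose, and that median was 0.20. ASNS was the 1 of 24 unfolded protein response genes past the rule, downwards, while the list median was 0.13. None of 32 proliferation genes was past the rule, and their median of -0.09 lay at percentile 0.05 of random lists. The reference genes lay at percentile 99.98, so a place in a tail is not particular to proliferation genes. None of 23 immediate early genes was past the rule (median 0.04).

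With 1 array left out, the wild-type count was 80 to 102, and 102 without the array that held the construct in channel 2. The count also moved by more than 1.5 times with other fold limits, from 20 genes at 3-fold to 199 at 1.5-fold.

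R367L changed the genes that wild type changed, and most by more. Of 13383 genes measured, 132 were past the rule, 125 higher and 7 lower, and all 59 wild-type genes were among them. S100A6 rose by 4.54 ± 0.09 (23.3-fold), MAL2 by 4.44, DHRS2 by 4.43 (21.5-fold), KRT19 by 4.28 and H19 by 3.86. LGALS3BP (3.52), SERHL2 (3.09), S100A16 (2.91), INHBB, an activin and inhibin subunit gene (2.83), and S100P (2.78) followed. The genes that fell were ASNS (-1.71 ± 0.07), ALOX15B (-1.69), TIMM17B (-1.46), CD1E (-1.38 ± 0.18), the serine synthesis gene PSAT1 (-1.25), CTH (-1.21) and the zinc finger gene ZBTB41 (-1.15). PSAT1 was at -1.03 with wild type, where it was not past the rule.

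Keratins, luminal genes and junction genes also had the most members past the rule with R367L, while the heat shock median exceeded that of junction genes. Of 17 keratins 6 rose, among them KRT19, KRT18 (2.52), KRT8 (1.87) and KRT7 (1.82), with a median of 0.33. Of 26 luminal genes 5 rose, FOXA1 (1.79), AGR2 (1.69), XBP1 (1.30), TFF3 (1.18, and 0.92 without the array in channel 2) and CA12 (1.01), with a median of 0.42. Of 22 junction genes 4 rose, SPINT1 (2.53), EPCAM (1.61), SPINT2 (1.53) and the claudin gene CLDN4 (1.33), with a median of 0.18. FASN (2.31) and SREBF1 (1.92) rose in a cholesterol list with a median of 0.13, and HSPA1A (1.87) in a heat shock list with a median of 0.33. Of 23 immediate early genes 3 rose, DUSP4 (1.40), FOS (1.21) and EGR1 (1.15), with a median of 0.07. RPL19 (1.43), WNT5A (1.11) and TFRC (1.74) each rose alone in lists with medians of -0.11, -0.04 and 0.10. In the unfolded protein response list XBP1 rose and ASNS fell, and the median was 0.12. None of 32 proliferation genes was past the rule, and their median was -0.14, below all random lists. With 1 array left out the count was 125 to 205, and 205 without the array that held the construct in channel 1.

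**Figure D2:**
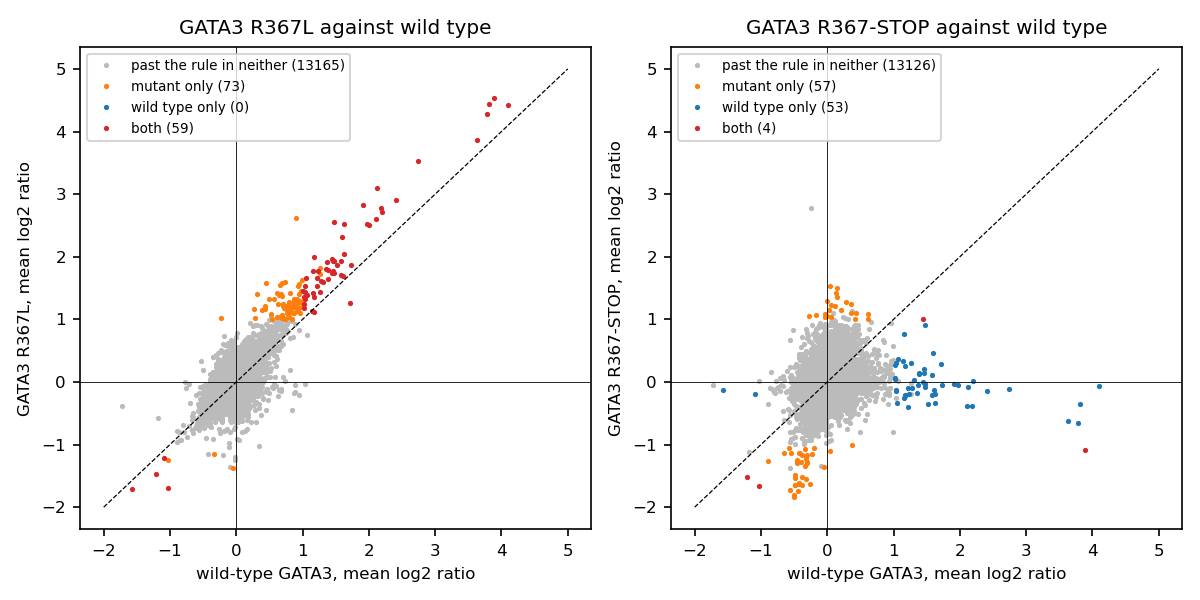
Mean log2 ratio over empty vector of each gene with R367L (left) and R367-STOP (right) against wild type, with colours for the genes past the rule and the dashed line at equal values. Of 57 wild-type genes with a value on all arrays, 54 have a mean larger in size with R367L, so higher genes lie mostly above the line and the 4 lower genes below it; with R367-STOP 24 of the 57 have the same direction.

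R367L against wild type compares the leucine substitution with the unchanged factor, within 1 day tag. The GATA3 transcript probes were also higher with R367L (3.28-fold against 2.36-fold over empty vector), and each construct is 1 sample. The substitution, the amount of GATA3 RNA and differences between the cultures therefore cannot be told apart. Of 13297 genes measured 9 were past the rule, 5 higher with R367L and 4 lower. The simulated comparison gave 12 false calls, so this count is not above that of the simulation. The simulation took the unmoderated spread of each gene on these arrays as its true spread, so its 12 calls are a rough figure. The higher genes were CEACAM6, a cell adhesion gene (difference 1.71 ± 0.28), MAP6 (1.25 ± 0.11), AZGP1 (1.14 ± 0.24), S100A4 (1.08 ± 0.16) and the mammary secretoglobin gene SCGB2A2 (1.08 ± 0.24). The lower ones were CD1E (-1.33 ± 0.25), SERPINB9 (-1.29 ± 0.30), VASP (-1.05) and ANP32D (-1.05 ± 0.22). SERPINB9 and ANP32D were not past the rule once the arrays were centred, which left 7 genes, 5 higher and 2 lower. Without the wild-type array in channel 2, AZGP1 was at 0.73, S100A4 at 0.82, SCGB2A2 at 0.73, SERPINB9 at -0.72 and ANP32D at -0.62, all below the limit. Without the R367L array in channel 1 the count was 79, without the other R367L array 23, and without either wild-type array 70 or 24. Over the 57 wild-type genes with a value on all arrays, the regression slope of R367L on wild type was 1.22, the median ratio was 1.24, and R367L was larger for 54.

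R367-STOP gave a different set of changes. Of 13314 genes measured 61 were past the rule, 23 higher and 38 lower. The genes that led with the other constructs were not higher: KRT19 was at -0.65 ± 0.10, DHRS2 at -0.06, MAL2 at -0.35 and H19 at -0.62, and S100A6 fell to -1.09 ± 0.09. The largest rises were in POLR2G, an RNA polymerase II subunit gene (1.53 ± 0.07), FAU, which encodes a ribosomal protein fused to a ubiquitin-like protein (1.499), BANF1, which acts in nuclear assembly (1.42), the co-chaperone gene STIP1 (1.35) and CYP26A1, a retinoic acid-degrading enzyme gene (1.29 ± 0.09). The chemokine receptor gene CXCR4 (1.28), LBHD1 (1.25), TRMT112 (1.23), MRPL11 (1.22) and NDUFV1 (1.15) followed. Of the 23 higher genes, 11 lie on chromosome 11, where 1.55 would be drawn in proportion to the genes measured, and 6 lie on chromosome 17, where 1.40 would be. Higher genes were uneven with the other constructs too. Chromosome 17 held 9 with wild type against 3.36 in proportion, and 17 with R367L against 7.63. Chromosome 8 held 5 against 1.92 and 10 against 4.37. Chromosome 11 held 1 against 3.71 and 8 against 8.42. The 11 on chromosome 11 lie among 145 neighbouring measured genes from LBHD1 to GAL. Without that segment, a choice made after the values were seen, 48 genes were past the rule, 12 higher and 36 lower.

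The genes that fell with R367-STOP were led by SLC9A3, a sodium and proton exchanger gene (-1.83 ± 0.08), ADAMDEC1 (-1.81), CCDC120 (-1.74), the peroxisomal enzyme gene EHHADH (-1.73) and ALOX15B (-1.67). GUCA2B (-1.65), the endosomal GTPase gene RAB5B (-1.65), OSBPL11 (-1.64), CAMKK1 (-1.64) and PAFAH2 (-1.63) followed. Of these 10 named genes, 8 carried a dye effect above 0.5 on the arrays of the other constructs, all but ALOX15B and CAMKK1. Of all 38 lower genes, 12 (31.6%) carried one, against 3.81% of all genes. Without the R367-STOP array in channel 1 the count was 130, with 82 higher and 48 lower, so the balance of directions turned. At 3-fold 11 genes were past the rule, all lower, and with each array at least 2-fold 32, 7 higher and 25 lower. At 1.5-fold there were 471, with 270 higher and 201 lower, so which direction led depended on the limit.

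**Figure D3:**
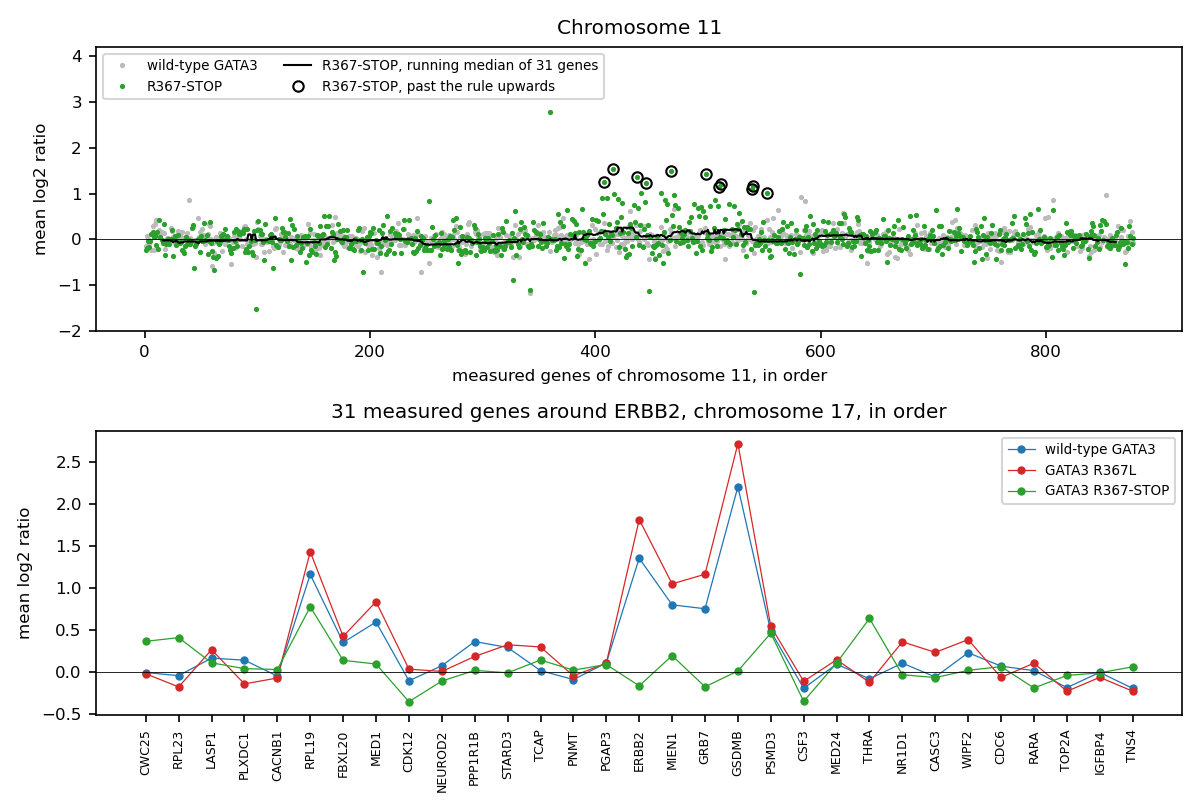
Mean log2 ratio in gene order, without coordinates: all measured genes of chromosome 11 (top, with wild type and R367-STOP, and the running median of R367-STOP over 31 genes) and 31 measured genes around ERBB2 on chromosome 17 (bottom, 3 constructs). On chromosome 11 the 11 circled genes past the rule lie together, and on chromosome 17 ERBB2, MIEN1, GRB7 and GSDMB lie above 0 with wild type and R367L and near 0 with R367-STOP.

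With R367-STOP, ribosomal protein genes had a median of 0.35, with 28 of 29 above 0 and none past the rule. HSPE1 (1.004 ± 0.10) was the 1 of 20 heat shock genes that rose, and the median was 0.24. NOG, a BMP antagonist gene (1.07 ± 0.13), and TFRC (1.001 ± 0.08) were the only ones past the rule in their lists, whose medians were -0.01 and 0.25. HSPE1 and TFRC fell below the limit when arrays were scaled (0.99 for both), and STIP1 and NDUFV1 no longer passed on each array. Without the array in channel 1, NOG was at 0.72 and HSPE1 at 0.87, below the limit as well. None was past the rule among keratins (median -0.10), luminal genes (-0.02), junction genes (-0.05), cholesterol genes (0.14), immediate early genes (-0.08), proliferation genes (-0.04) and unfolded protein response genes (0.01). Among 26 mesenchymal and matrix genes, with none past the rule, the median was -0.17, at percentile 0.08, and VIM was at -0.67 and COL3A1 at -0.66. That list had medians of -0.04 with wild type and -0.02 with R367L.

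Some lists had no gene past the rule with any construct. In wild type, R367L and R367-STOP order, medians were -0.02, 0.01 and -0.09 for 21 T cell and T helper 2 genes, and 0.01, -0.03 and 0.08 for 19 erythroid and megakaryocyte genes. For 10 GATA family and cofactor genes they were -0.11, -0.04 and -0.08, with TRPS1 at 0.64, 0.89 and -0.11. For 20 trophoblast genes they were 0.04, 0.05 and -0.06, with PLAC1 at -0.31, -0.31 and 0.84. For 16 kidney genes they were -0.03, -0.03 and -0.12, and LHX1 was at -0.80 with R367-STOP. They were -0.02, 0.03 and -0.02 for 20 neuronal genes, 0.01, -0.08 and 0.00 for 14 cell cycle inhibitors, and 0.02, 0.01 and -0.01 for 32 interferon response genes. Of the largest members, MAF was at -0.71 and STAT6 at 0.55, TAL1 at 0.42 and KLF1 at -0.34, WNT11 at 0.38 and GAP43 at -0.77, and CDKN1A at -0.40, all with R367-STOP. With R367L, TFAP2C was at 0.84, TH at 0.55, GADD45A at -0.39, ISG20 at 0.68 and B2M at 0.65. BIRC5 was at 0.66 and MCM2 at -0.52 with R367-STOP.

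**Figure D4:**
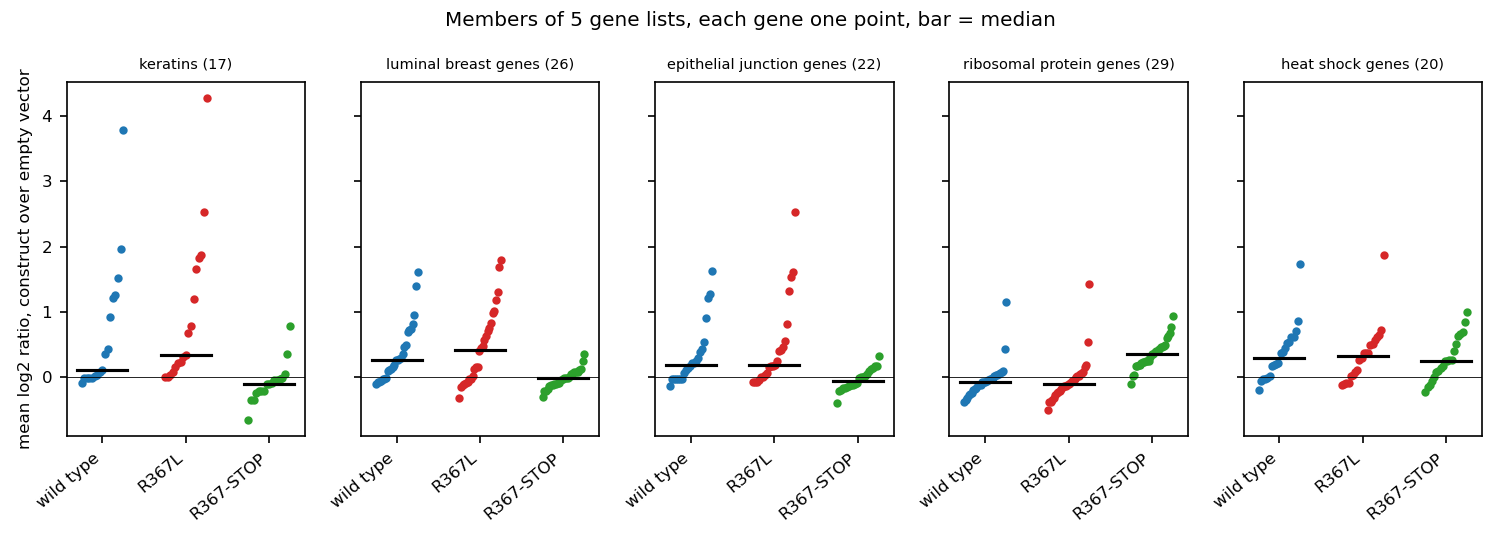
Mean log2 ratio over empty vector of each measured member of 5 gene lists, by construct, with the bar at the median. Keratins, luminal and junction genes have members far above 0 with wild type and R367L, and ribosomal protein genes have a median of 0.35 with R367-STOP.

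Compared with wild type, R367-STOP had 26 genes higher and 75 lower of 13240. The largest negative differences were in S100A6 (-4.97 ± 0.13), KRT19 (-4.43), H19 (-4.26), MAL2 (-4.16) and DHRS2 (-4.15). The largest positive ones were in POLR2G (1.48 ± 0.10), ASNS (1.45), the growth factor gene MDK (1.35), FAU (1.35) and MID1 (1.33). Compared with R367L, R367-STOP had 36 genes higher and 128 lower of 13083, led by S100A6 (-5.63 ± 0.13), KRT19 (-4.94), MAL2 (-4.79), DHRS2 (-4.49) and H19 (-4.48). The largest positive differences were in MS4A6A (3.28 ± 1.20, from arrays that disagreed), ASNS (1.58), CD1E (1.53), POLR2G (1.46) and FAU (1.36). Over the 57 wild-type genes the slope of R367-STOP on wild type was -0.03, with 24 in the same direction, 3 of them past the rule, and S100A6 past it in the opposite direction. Taken over the genes past the rule with R367-STOP, most of which were not past it with wild type, the slope was 0.85. Choosing genes for their size with R367-STOP can itself raise that slope, so it is not a measure of a kept wild-type response. Without wild-type arrays in turn the R367-STOP against wild-type count was 153 each time, and without the R367-STOP array in channel 1 it was 194 (92 higher and 102 lower), against 101. For R367-STOP against R367L, it was 277 without that array (121 higher and 156 lower) and 289 without the R367L array in channel 1, against 164. At 1.5-fold the directions were 254 higher and 296 lower against wild type and 410 and 430 against R367L, so the lean towards lower genes was weaker there. These differences carry the day tag as well as the construct.

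The constructs were then compared across 13014 genes, which are not independent replicates. Wild type and R367L correlated at r = 0.79 (Spearman 0.62), with 53 genes higher in both against 0.493 for independent lists and 4 lower in both against 0.0022. Wild type and R367-STOP correlated at r = 0.20 (Spearman 0.22), with 1 gene higher in both and 2 lower. R367L and R367-STOP correlated at r = 0.13 (Spearman 0.12), with 1 higher and 3 lower. All constructs share the control pool: simulated unchanged populations correlated at 0.26 with a pool of 3 and 0.50 with a control of 1. The covariances were 0.0458, 0.0113 and 0.0096, against 0.0179 and 0.0348 in these simulations if all the R367-STOP variance were such spread. The pool could not be split, so part of the likeness may come from it. Genes past the rule with all 3 constructs were TFRC upwards and ALOX15B and TIMM17B downwards. With R367-STOP, TFRC was at 0.92 without the array in channel 1 and 0.99 when arrays were scaled. With wild type, ALOX15B was at -0.97 without the array in channel 1, so TFRC and ALOX15B lie at the limit. TIMM17B was at -1.21, -1.46 and -1.53 with wild type, R367L and R367-STOP.

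No gene passed an adjusted p of 0.05 by limma in the mean of the 3 constructs, and 2036 of 13014 had an unadjusted p under 0.05. The smallest adjusted p by limma was 0.125. Leaving out R367-STOP gave 775 genes, 484 higher and 291 lower, leaving out R367L gave 7, and leaving out wild type gave 2. The test asks only for changes alike in all constructs, and the control pool's own spread is not in it. Wild type and R367L, the constructs left without R367-STOP, also share a day tag, so a shift of that day would be counted in the 775 genes.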

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

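The test of GATA3 RNA amount and the count of neighbouring-gene windows were chosen after the results were seen, while the tests on the median of the ERBB2 neighbours and on the ratio of the excess were fixed before.

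S100A6 rose by 3.88 with wild-type GATA3 and by 4.54 with R367L and was at -1.09 with R367-STOP, on every array of each construct. The opposite direction drew attention to it, and the difference was not tested, since each construct has 1 sample. Keratin, luminal and junction genes past the rule with wild type and R367L were not past it with R367-STOP.

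For that pattern, a candidate explanation is that breast cancer cells with extra copies of the ERBB2 region were mixed into both cultures; the test fixed in advance asked for a median of the ERBB2 neighbours of at least 0.3, with 0.15 as the bound for dropping the idea, and the lower median was 0.10. That median was taken over 17 genes of a list, ERBB2 itself among them. GSDMB was left out of the list in advance, and RPL19 was not in it. Both were past the rule with wild type and R367L, so the median leaves out high neighbours. The median lay under the bound, so by the criterion written in advance the idea would be dropped. The resampling interval of -0.06 to 0.48 with wild type spans the bound, but an interval was not part of that criterion. A count picked only after that median had failed, so weak evidence, found 4 of the 17 genes 1.5-fold higher with both, ERBB2 included. As many or more were found in 39 of 12582 windows elsewhere (0.310%), which were not placed around a gene of interest. A fixed share of other cells would give 1 ratio of excess between R367L and wild type. Over 53 genes the SD of its log2 value was 0.36, 1.70 times the 0.21 that array error gives. That lay between the limits of 1.5 and 2 set in advance, so the test did not decide. A robust SD, which single genes sway less, was 0.26, nearer to the 0.21 from array error. S100A4 and TRGV9, picked out after their values were seen, lay over 2 SD from the median ratio. How much of the 1.70 came from few genes was not settled, and a robust SD was not part of that criterion. Less GATA3 RNA with R367-STOP is argued against, since its transcript probes were 0.21 higher than with wild type, although the other probe, 14800, whose arrays lay on opposite sides of 0, was lower (-0.07 against 0.40), and the average over all probes was 0.94 against 0.96. Mixed cells cannot be told apart from a response to GATA3 that the truncated protein lacks, which stays open and untested, because each construct was 1 sample and R367-STOP had its own day tag.

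Probes with no gene listed here were outside the comparisons. Of these, 14 were past the rule with wild type, 26 with R367L and 29 with R367-STOP.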

How the results depend on the processing

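Comparisons are given in the order wild type, R367L and R367-STOP against empty vector, R367L against wild type, R367-STOP against wild type and R367-STOP against R367L, with reported counts of 59, 132, 61, 9, 101 and 164. At a mean of 1.5-fold they were 199, 378, 471, 133, 550 and 840, and at 3-fold 20, 47, 11, 1, 21 and 43. With each probe counted separately they were 108, 226, 101, 15, 175 and 261. Without the noisiest 25% of genes, wild type gave 36, R367L 75, R367L against wild type 2, R367-STOP against wild type 60 and R367-STOP against R367L 97. With each array at least 2-fold, R367-STOP gave 32 and R367L against wild type 3, and with the mean alone the latter gave 16. With 1 array left out, the lowest and highest counts were 80 and 102, 125 and 205, 90 and 130, 23 and 79, 146 and 194, and 170 and 289. The remaining array has no partner that must pass too; the count was higher in most of these settings, and lower for R367L without its array in channel 2. Leaving out wild type, R367L or R367-STOP from the limma test of the mean gave 2, 7 or 775 genes against 0. The R367L slope of 1.22 was 1.27 with genes chosen on channel 1 and measured on channel 2, 1.12 the other way round, and 1.28 with genes chosen by R367L. The R367-STOP slope of -0.03 was 0.0544 and 0.0384 with genes chosen on channel 1 and on channel 2, and 0.85 with genes chosen by R367-STOP. Choosing genes by the mutant can itself raise its slope. Other than for looser, stricter or smaller sets by construction, the cause was not tested. The other 51 values of counts and slopes, among them those with arrays centred or scaled, the chromosome 11 segment left out or the dye effect removed, stayed within 1.5 times or within error. Of the named-gene values, 24 dropped below the rule, 17 came to pass it, 183 moved past their error without crossing it and 1018 did not, and none that was past the rule changed direction. All 120 list medians, tried only with arrays centred or scaled, moved by no more than the median SE of their member genes. The arrays had already been centred, so this was a weak check, and no array was left out for list medians. With matched random lists, 2 of 60 percentiles crossed into the outer tail. Removal of the dye effect, the segment, genes with large dye effects and scaled list medians were chosen after seeing the data. A variance prior with a trend was not run, since intensities were not used here. No paired analysis was possible because each construct is 1 sample and replicate numbers only name the arrays of a dye swap. What signal over background limits could not be assessed.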

Other observations

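Tests of the gene families wherever they lie, of the control pool and of the dye effect on lower genes were chosen after the results were seen. The genes named in this part outside the named rule were chosen after their values were seen.

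Beyond the lists of the report, runs of neighbouring genes were higher with wild type and R367L. In windows of 21 neighbouring genes, 6 S100 genes on chromosome 1, 6 genes on chromosome 17 (RPL19, MED1, ERBB2, MIEN1, GRB7 and GSDMB) and 5 MAGEA genes on chromosome X were 1.5-fold higher with both. Over 1000 shufflings of positions the highest window had 4 at the 95th percentile and 5 at most. These windows were examined after the values were seen, and families such as S100 and MAGEA have probes that can share signal. S100A14 was at 2.11 and 2.61, S100A9 at 1.24 and 1.78 and S100A8 at 0.70 and 1.22 with wild type and R367L. The cancer-testis gene MAGEA4 was at 1.04 and 1.44 and MAGEA1 at 0.80 and 1.14, and the 8 MAGEA genes had a median of -0.07 with R367-STOP. The imprinted genes MEST and PEG10 were at 1.63 and 2.05 and at 1.31 and 1.60, while CDKN1C, another imprinted gene, was at 0.05 and -0.02. The surface protein genes CD24 (1.06 and 1.65), CD9 (1.45 and 1.77) and VTCN1 (1.58 and 1.71) followed the same pattern, and were at -0.34, 0.21 and 0.11 with R367-STOP.

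For 4 families picked after their values were seen, and not set against random lists, medians with R367-STOP were 0.37 for 65 ribosomal protein genes, 0.37 for 63 mitochondrial ribosomal protein genes, 0.37 for 39 NADH dehydrogenase genes and 0.29 for 38 proteasome genes. Members past the rule upwards were 0, 1, 1 and 0. The same groups were at -0.04, 0.13, 0.13 and 0.17 with wild type and at -0.09, 0.09, 0.14 and 0.12 with R367L. Reference genes were also above 0 with R367-STOP, with a median of 0.25 (percentile 99.9), against 0.20 with wild type and 0.10 with R367L. Among them GAPDH was at 0.40, EEF1A1 at 0.38 and ACTB at 0.01 with R367-STOP. Higher values are therefore not particular to these families.

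ASNS, CTH and PSAT1 were lower with wild type and R367L, and all serve amino acid synthesis. The hypothesis was that the amino acid starvation response, driven by ATF4, was less active in both cultures. A list of 31 other targets, without ASNS, CTH, PSAT1, AARS1 and SLC3A2, whose values had been seen, was fixed before it was measured, and 6 of the 26 measured members are also unfolded protein response genes. The median was -0.33 with wild type and -0.39 with R367L, below all 10000 random lists in both, with 23 and 22 members below 0. The random lists were not matched on expression, and the reference genes lay in the high tail with wild type (percentile 99.98). PHGDH was at -0.75 and -0.88, MTHFD2 at -0.85 and -0.93 and SARS1 at -0.63 and -0.74, while TRIB3 went the other way, at 0.40 and 0.59. With R367-STOP the median was -0.11, at percentile 1.82, with 17 of 26 below 0, so it lay in the low tail as well. The values are consistent with a less active response in the wild-type and R367L cultures, while part of the shift may come from the shared control pool, and medium, cell density and GATA3 stay open.

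The 11 genes higher together on chromosome 11 with R367-STOP could come from extra copies of a segment in those cells. The other 134 genes of the segment had a median of 0.11, between the bounds of 0.1 and 0.3 set in advance; it lay above all 10000 random lists (at most 0.0755), but a window elsewhere reached 0.13, and the segment's limits were drawn from the higher genes themselves, so the test leaves this open. Loss of the segment from the control pool is argued against if all arrays held the same pool, since the 11 genes had medians of 0.13 with wild type and 0.14 with R367L (intervals up to 0.20 and 0.32) and 1.23 with R367-STOP. That comparison was chosen after the values were seen, because the segment medians of 0.0325 and 0.0435 met both criteria set in advance and decided nothing. Higher values of a wider set of families (ribosomal, mitochondrial, proteasome, RNA polymerase and similar symbols) could also account for part of it: the 7 members in the segment were 0.19 above the 289 elsewhere (median 0.33), with an interval of -0.35 to 0.90, so the family and copy explanations cannot be told apart. Genes past the rule were not left out of those 7, and the segment's limits were drawn from such genes, which can raise that difference. No biological explanation was tested.

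The genes lower with R367-STOP may include signal that does not come from the named gene. Of 38, 12 (31.6%) had a dye effect above 0.5, against 3.81% of all genes, and these 12 genes had nearly the same value, -1.64 with an SD of 0.13, and -0.41 and -0.63 with wild type and R367L. Of all 502 genes with such a dye effect and a value for every construct, 35.1% were below 0 with R367-STOP and the median was 0.10, so a large dye effect does not in general go with a fall. The limits of that test were set after these profiles had been seen, so it was lenient. The other 26 are not addressed by it, and a biological explanation was not tested.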
